A study of Homo sapiens with 2 samples.

How the data were processed

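RNA was extracted with Trizol and made into stranded total RNA libraries, per the labels' protocols. The labels describe 2 samples of HEK293 Flp-In T-Rex cells, numbered as replicates, while the extraction text calls the cells HEK293T. The submitters' processing notes name Trim Galore 0.6.4, Bowtie2 2.4.2, STAR 2.6.0b and the genome build GRCh38, with no role or order. The counting program and the annotation release are not given in the sources used here. Nor is the treatment of strand, of reads in introns and of reads that match several genes. These settings can bear on genes with near-identical copies, such as HSPA1A and HSPA1B, on genes with processed pseudogenes, on overlapping genes and on genes with long introns.

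The authors deposited 1 table of 332 chaperome genes with Ensembl identifiers and genomic positions. Per the file headers it holds 1 column per replicate and a mean RPKM, and the deposited values of the replicate columns are whole-number read counts. The replicate columns carry the prefix NHS, which the sources used here do not define. The deposited RPKM equals the mean over both replicates of the count per kilobase of the gene's genomic span, introns included, and scaled to a library total (RPM). The totals are not printed in the table. They were recovered by least squares from the counts, spans and mean RPKM, and came out as 6828264 and 4445676 reads, with a largest relative misfit of 7.62e-14 over the 332 genes. What these totals count (all reads, aligned reads or reads in genes) is not given in the sources used here. The RPKM of each replicate was then computed from its counts and total. The design had assumed an RPKM column for each replicate. With 1 group there was nothing for a count model of groups to test, so the RPKM analysis was kept as planned.

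Gene positions were compared with GENCODE 29 on GRCh38. All 332 identifiers were found, 330 with the same name, and starts were equal for 202 genes and ends for 203. One row whose name differs, UTX, carries the identifier that GENCODE gives to LEUTX. Exonic length was the union of a gene's exons in GENCODE 29. A stretch that is an intron of 1 transcript but lies in an exon of another stays in this length. For some genes it was about as long as the span, as for FKBP11 with 4957 against 4956 bases. Values per kilobase of exon assume that the counts hold exonic reads only. No genome sequence was used. The share of the HSPA1A and HSPA1B transcripts that differs was counted from annotated transcript sequences in windows of 50 bases, since the read length is not given in the sources used here.

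Before the data were examined, 16 gene lists, the tests and the alternatives were fixed. For each list the median of log2(mean RPKM + 1) was placed as a percentile among 10000 random lists of the same size drawn from the table, with a two-sided tail share, Benjamini-Hochberg adjustment over the 16 lists and a threshold of 0.05. The smallest tail share this allows is 0.00020 before adjustment. HSP70 genes were compared by the difference of mean log2(RPKM + 1) from the highest member, called where the sign was the same in both replicates and the size exceeded 1.96 standard errors. The standard error used the replicate SD pooled over the table, 0.091 on the log2 scale. Genes were counted at a mean of at least 1 RPKM. Shares of a library have 95% Wilson intervals.

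The genes named were those set by a fixed rule: all HSP70 genes, the 10 genes with the highest mean RPKM, the highest gene of each list, the 3 genes of at least 1 RPKM with the largest log2 ratio between the replicates, tissue-restricted genes of at least 1 RPKM (0 genes), and all HSP90 and CCT ring genes. The rule gave 38 genes. Other genes named, among them CANX, HSPD1, HSPE1, PPIA and FKBP5, were chosen after their values were seen. The exact binomial test between the libraries, with each library's total as its exposure, the lists without HSPA1A and HSPA1B, and all calculations with exonic length were also chosen after the data were seen. The log2 ratios of the binomial test are of library-scaled reads with 0.5 reads added, so they differ slightly from ratios of RPKM + 1.

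The alternatives were thresholds of 0.5 and 5 RPKM, a pseudocount of 0.1 RPKM, genes of at least 1 RPKM only, random lists drawn from outside the list, each replicate left out in turn, HSPA1A and HSPA1B summed, replicate 2 rescaled to a median ratio of 1 and duplicate symbols removed. The tests were tried on simulated data. In Poisson counts drawn for 332 genes from the real means and library totals, the binomial test recovered 53.0% of genes changed 1.5-fold. It recovered 82.0% of genes changed 2-fold. For genes with at least 100 reads these shares were 81.3% and 98.7%, and 1 of 132 unchanged genes was called. These counts hold counting error only. The real libraries differed by more than that, so these rates need not hold for them. At an unadjusted tail share under 0.05, the list test called 2 of 40 unshifted lists of 8 genes and 37 of 40 lists shifted by 2 on the log2 scale. The real lists were called after adjustment. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.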

Results

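The series asked how HSP70, the main cytosolic ATP-driven chaperone, binds RNA and acts on transcription by RNA polymerase III. The part analysed here measured the RNA levels of chaperone genes in cultured cells. Total RNA was sequenced from HEK293 Flp-In T-Rex cells, a line derived from human embryonic kidney that carries a recombination site for stable insertion of a transgene under a tetracycline-controlled promoter. The labels put both libraries in 1 group, as replicates 1 and 2, so no treated group could be set against a control. The design text describes 2 derived lines, with tagged GFP or tagged HSPA1A, and induction with tetracycline for 16 hours. The sample labels do not say whether either derived line was the one sequenced, nor whether it was induced.

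The table held 332 genes of the chaperome, the set of chaperones, co-chaperones and folding enzymes. The library totals behind the authors' RPKM were 6828264 reads for replicate 1 and 4445676 reads for replicate 2. Chaperome genes took 192352 reads in replicate 1, which was 2.82% of the library (95% Wilson interval 2.80 to 2.83), and 126085 reads in replicate 2, which was 2.84% (2.82 to 2.85). The median gene had 198 reads in replicate 1 and 129 in replicate 2. A gene with 0 reads could still have been present at up to 3 counts, or 0.439 RPM in replicate 1 and 0.675 RPM in replicate 2. These intervals and limits cover counting error only.

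The first question was how the HSP70 genes ranked against each other. HSPA8, the constitutive cytosolic HSP70 (ENSG00000109971, chromosome 11, 123057489 to 123063230, minus strand, GRCh38), was the highest gene of the whole table at 394 ± 6.95 RPKM (SD, n = 2). HSPA1B, a stress-inducible HSP70 gene without introns (ENSG00000204388, chromosome 6, 31827738 to 31830254, plus strand), came next at 311 ± 15.9 RPKM per kilobase of genomic span. With exonic length HSPA8 stayed highest, while HSPA1B, at 311 RPKM, came after HSP90AB1 (330) and HSP90AA1 (313). HSPA5, the HSP70 of the endoplasmic reticulum, stood at 30.5 ± 9.0 RPKM, and HSPA9, the mitochondrial HSP70, at 22.7 ± 0.662 RPKM. HSPA1A, which encodes nearly the same protein as HSPA1B (ENSG00000204389, chromosome 6, 31815543 to 31817946, plus strand), had 1 read in replicate 1 and 3 reads in replicate 2.

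Per kilobase of genomic span, the HSP110-type members were lower than HSPA8, HSPA1B, HSPA5 and HSPA9. HYOU1 of the endoplasmic reticulum stood at 8.45 ± 0.706 RPKM, HSPA4 at 5.06 ± 0.0683 RPKM, HSPH1 at 4.23 ± 0.220 RPKM and HSPA4L at 1.09 ± 0.0698 RPKM. HSPA13 was at 3.11 ± 0.155 RPKM and HSPA14 at 1.13 ± 0.142 RPKM. The remaining members were under 1 RPKM, with HSPA2 at 0.413 ± 0.160, the heat-induced HSPA6 at 0.268 ± 0.0267, HSPA12A at 0.163 ± 0.00108, HSPA1L at 0.0129 ± 0.0183 and HSPA12B at 0.00358 ± 0.00507 RPKM. In all, 10 of the 16 HSP70 genes reached 1 RPKM per kilobase of genomic span. With exonic length 11 did, among them HSPA12A at 2.46 RPKM from 200 and 129 reads. HSPA6, with 4 and 3 reads, stood at 0.266 RPKM with exonic length, so the order of this pair turned. HSPA1L and HSPA12B each had 1 read in replicate 1 and 0 reads in replicate 2.

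On the log2(RPKM + 1) scale, HSPA8 exceeded HSPA1B by 0.34 (SE 0.091), with 0.27 in replicate 1 and 0.41 in replicate 2. All 15 other HSP70 genes were below HSPA8 in both replicates by more than the 95% limit of the standard error, which came from the replicate spread pooled over the genes of the table. An exact test on 2 replicates cannot go below 0.5, so no p-value is given for this order. The order of the first pair depends on how reads shared by HSPA1A and HSPA1B were counted, which the sources used here do not give. If the HSPA1B reads came only from the parts of its transcript that HSPA1A lacks, with exonic length, the difference turned to -1.22 (SE 0.125). Reads of a tagged HSPA1A transgene, if that line was sequenced, could also have been counted at HSPA1B. The order of HSPA5 and HSPA9 was not resolved, since their RPKM ratio was 1.35 ± 0.435 (SD, n = 2) per kilobase of genomic span and 0.848 ± 0.274 per kilobase of exon. HSPA4 also came level with HSPA5 per kilobase of exon, at 53.5 ± 0.722 against 51.0 ± 15.0 RPKM.

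**Figure D1:**
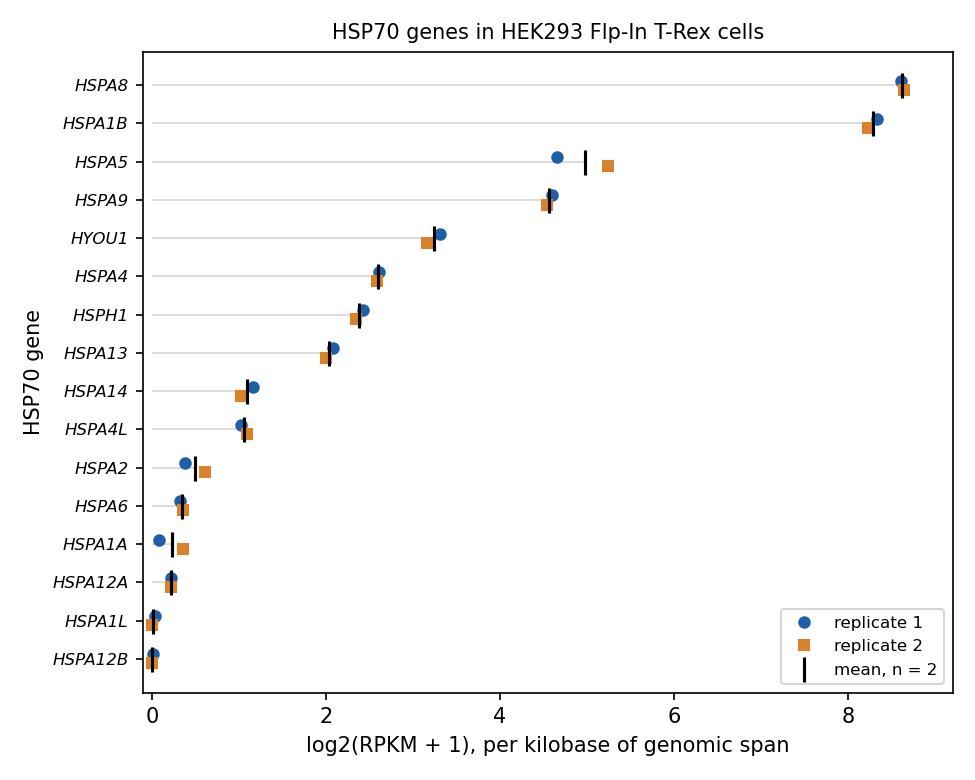
RPKM of the 16 HSP70 genes on the log2(RPKM + 1) scale, with circles for replicate 1, squares for replicate 2 and a bar for the mean of both. HSPA8 and HSPA1B lie far to the right of the other genes, with means of 394 and 311 RPKM, and HSPA5 shows the widest gap between the replicates.

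The next question was how the HSP90 genes and the CCT ring compared with the rest of the chaperome. HSP90AB1, the constitutive cytosolic HSP90, stood at 128 ± 1.51 RPKM, HSP90B1 of the endoplasmic reticulum at 32.5 ± 0.128 RPKM, the stress-inducible HSP90AA1 at 27.9 ± 6.76 RPKM and the mitochondrial TRAP1 at 2.75 ± 0.0708 RPKM. All 4 HSP90 genes reached 1 RPKM, and their median of 30.2 RPKM lay at percentile 99.95 among random lists of the same size (adjusted tail share 0.00320). All 8 subunits of CCT, the ring that folds actin and tubulin, were above 10 RPKM, from CCT5 at 42.3 ± 0.00203 and TCP1 at 41.4 ± 1.18 down to CCT4 at 16.7 ± 0.850 and CCT3 at 10.3 ± 0.736 RPKM. Between these, CCT2 stood at 28.6, CCT8 at 28.1, CCT6A at 26.2 and CCT7 at 21.4 RPKM. The ring's median of 27.1 RPKM was above all 10000 random lists (adjusted tail share 0.00107, the smallest found).

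Both orders within these groups depended on the gene length. HSP90AB1 exceeded HSP90AA1 4.72 ± 1.20 times per kilobase of genomic span, but 1.09 ± 0.277 times per kilobase of exon, and HSP90AA1 had more reads in both libraries, with 9290 and 8556 against 6780 and 4341. CCT5 was 4.11 ± 0.293 times CCT3 per kilobase of genomic span and 0.790 ± 0.0563 times CCT3 per kilobase of exon, so the order turned. HSP90 genes have processed pseudogenes, as do HSPA8 and PPIA, so their levels are uncertain where reads could match both.

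Among the other families, the wider list of chaperonins had 11 of 15 measured genes at 1 RPKM or more and a median of 16.7 RPKM, above all random lists (adjusted tail share 0.00107). It included the mitochondrial HSPD1 at 26.6 RPKM and its cofactor HSPE1 at 6.39 RPKM. The heat-inducible list, genes that the heat shock factor HSF1 can induce, had 13 of 17 at 1 RPKM or more and a median of 5.51 RPKM (percentile 99.99, adjusted tail share 0.00192). Its highest gene was HSPA8 at 394 RPKM, called constitutive above, so the level of the list alone does not show a stress response. HSPA6, HSPA1A, BAG3 and CRYAB of this list were under 1 RPKM. BAG3 had 114 and 72 reads and stood at 5.99 RPKM with exonic length, where 14 of 17 genes reached 1 RPKM. The small heat shock proteins were lower than random lists, with 1 of 10 genes reaching 1 RPKM (percentile 0.010, adjusted tail share 0.00160): HSPB1 at 2.02 ± 0.680 RPKM, from 17 and 18 reads. Of the 23 tissue-restricted genes measured, known mainly from testis, muscle, lens or retina, 0 reached 1 RPKM (adjusted tail share 0.00107), and CLGN was the highest at 0.470 ± 0.0483 RPKM. With exonic length CLGN was the 1 gene of this list to reach that level, at 5.89 RPKM. HSPB2, HSPB3, HSPB7, HSPB9, ODF1 and CRYAA were in both the small heat shock and the tissue-restricted list. The wider chaperonin list held all 8 CCT ring genes. The calls within each of these pairs of lists are therefore not independent.

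The nucleotide exchange factors of HSP70, the co-chaperones of HSP90 and the mitochondrial chaperones were also higher than random lists, but less firmly. Of the exchange factors, 12 of 14 reached 1 RPKM, led by BAG5 at 11.0 ± 0.416 RPKM (list percentile 99.67, adjusted tail share 0.0155). Of the HSP90 co-chaperones, 20 of 25 did so, led by the ubiquitin ligase STUB1 at 44.2 ± 1.40 RPKM (percentile 99.38, adjusted tail share 0.0272). Of the mitochondrial genes, 14 of 20 did so, led by the prohibitin PHB2 at 38.4 ± 0.163 RPKM (percentile 98.85, adjusted tail share 0.0412). The leading genes are those by genomic span: with exonic length HSPA4 (53.5 RPKM) exceeded BAG5 (12.8), PTGES3 (96.7) and FKBP4 (53.7) exceeded STUB1 (50.5), and HSPD1 (189) exceeded PHB2 (83.8). All 3 calls were lost with exonic length, at adjusted tail shares of 0.129, 0.0722 and 0.0742, and all 3 were lost when only genes of at least 1 RPKM were kept.

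The other 7 lists did not pass the threshold of 0.05. They were the HSP70 genes (percentile 96.07, adjusted tail share 0.115), class A J-domain proteins (3 of 4 genes at 1 RPKM or more, adjusted tail share 0.238), class B (4 of 13, 0.718), class C (11 of 32, 0.326), prefoldin (6 of 9, 0.318), the folding machinery of the endoplasmic reticulum (22 of 40, 0.326) and tetratricopeptide-repeat proteins (28 of 68, 0.0771). The J-domain proteins, which deliver clients to HSP70, were led, per kilobase of genomic span, by DNAJA1 at 12.7 ± 0.799, DNAJB9 at 2.68 ± 0.171 and DNAJC19 at 4.16 ± 0.267 RPKM. The lectin chaperone CALR led the endoplasmic reticulum list at 77.0 ± 1.81 RPKM and UXT the prefoldin list at 4.66 RPKM. With exonic length DNAJA1 and CALR stayed highest, while DNAJB1 (17.1 RPKM) exceeded DNAJB9 (4.70), DNAJC8 (35.8) exceeded DNAJC19 (7.03) and VBP1 (54.6) exceeded UXT (27.7). The counts at 1 RPKM or more then became 7 of 13 for class B, 26 of 32 for class C, 8 of 9 for prefoldin, 37 of 40 for the endoplasmic reticulum and 48 of 68 for tetratricopeptide-repeat proteins. With exonic length the tetratricopeptide-repeat list lay below the random lists (adjusted tail share 0.0485). The lists overlap, genes are not independent replicates, and the tail shares describe these 2 libraries.

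**Figure D2:**
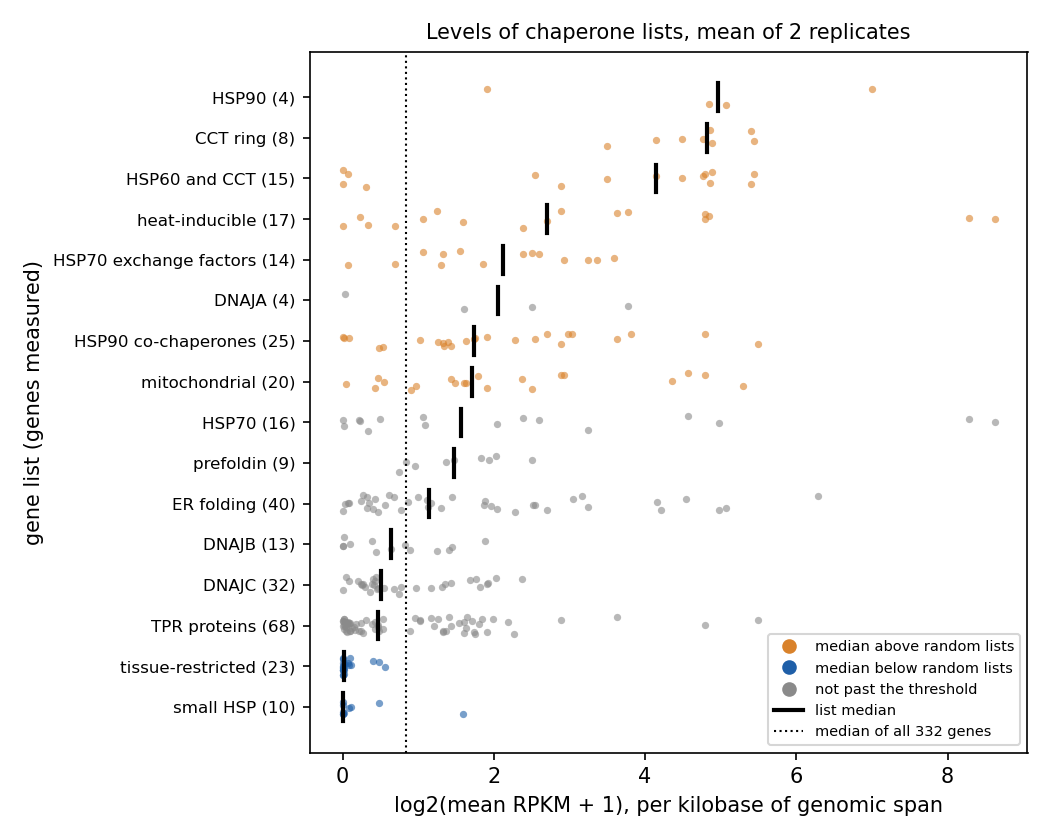
Levels of the 16 gene lists on the log2(mean RPKM + 1) scale, with 1 point per gene, a thick bar for each list's median and a dotted line for the median of all 332 genes. Lists in orange lie above random lists and lists in blue below them, and the CCT ring and HSP90 genes lie highest.

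The third question was how many chaperome genes were detected. At a mean of at least 1 RPKM, 154 of 332 genes were counted (46.4%), with 156 in replicate 1, 151 in replicate 2 and 150 in both. HSPA8, HSPA1B and HSP90AB1 were the 3 genes above 100 RPKM, 30 genes lay from 10 to 100 RPKM and 121 from 1 to 10 RPKM. Another 105 genes lay from 0.1 to 1 RPKM, 61 lay above 0 and under 0.1 RPKM, and 12 had 0 reads in both libraries. The authors' length is the genomic span with introns, a median of 6.37 times the exonic length. With exonic length 247 genes (74.4%) reached 1 RPKM. At a fixed threshold a shorter length can only raise a gene's value, so this rise says nothing on the order of genes. Spearman's rho between the 2 values was 0.888 across genes.

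The summed RPKM was concentrated in few genes. The 10 highest were HSPA8, HSPA1B, HSP90AB1, CALR, STUB1, CCT5, TCP1, PHB2, HSP90B1 and HSPA5, and they held 58.0 ± 0.131% of it (SD, n = 2). HSPA8 alone held 19.7% in replicate 1 and 20.4% in replicate 2. It held 7.93% and 8.07% of the chaperome reads, which are not divided by length, so longer transcripts weigh more there. With exonic length the 10 highest genes held 36.8% and with reads alone 36.2%, and 5 of the 10 genes were shared with the list by genomic span in each case.

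**Figure D3:**
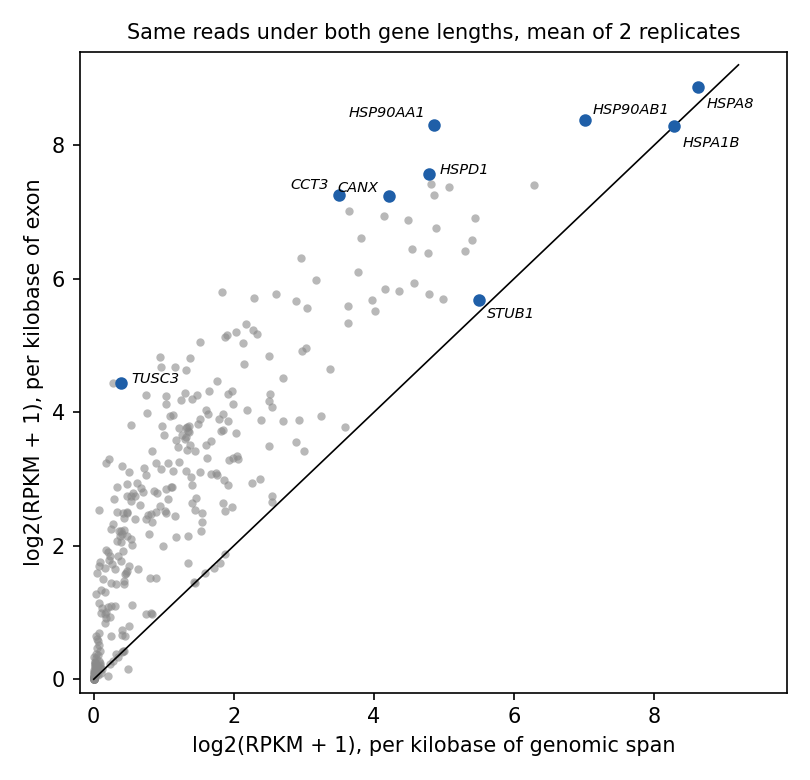
Mean RPKM of both replicates per kilobase of genomic span (x axis) against the same reads per kilobase of exon (y axis), both as log2(RPKM + 1), for 332 genes, with selected genes named. Genes above the line have a genomic span longer than their exonic length, such as HSP90AA1, at 27.9 RPKM by span and 313 by exon. The intronless HSPA1B lies on the line.

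The replicates were close across genes. Over the 332 genes, Pearson's r of log2(RPKM + 1) was 0.996 and Spearman's rho was 0.980, across genes that are not independent replicates. The SD of the log2 ratio was 0.13, and 0 genes differed by more than 2-fold on that scale, while 7 did with a pseudocount of 0.1 RPKM. Among genes of at least 1 RPKM, HSPA5, HSP90AA1 and HSPB1 differed most, higher in replicate 2 by 0.59, 0.48 and 0.46 on the log2(RPKM + 1) scale. The counts differed by more than sampling noise (chi-square 1284 over 275 genes with at least 10 reads, p = 7.03e-130), so the libraries were kept as 2 replicates.

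Counting error alone did not account for 15 genes in an exact binomial test between the libraries with Benjamini-Hochberg adjustment, 6 higher and 9 lower in replicate 2, and 55 genes had an unadjusted p under 0.05. HSP90AA1 (log2 ratio 0.50, adjusted p = 6.99e-115, exact binomial test) and HSPA5 (log2 ratio 0.61, adjusted p = 2.92e-20) were higher in replicate 2, and HSPA1B (log2 ratio -0.10, adjusted p = 0.0261), CCT2 (adjusted p = 0.0153) and CCT3 (adjusted p = 0.00264) were lower. HSPB1, with 17 and 18 reads, did not pass. The test compares 2 libraries of 1 group. The labels do not say that the replicates came from separate cultures, so this spread and every p-value measure only the difference between these samples, which may be technical.

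**Figure D4:**
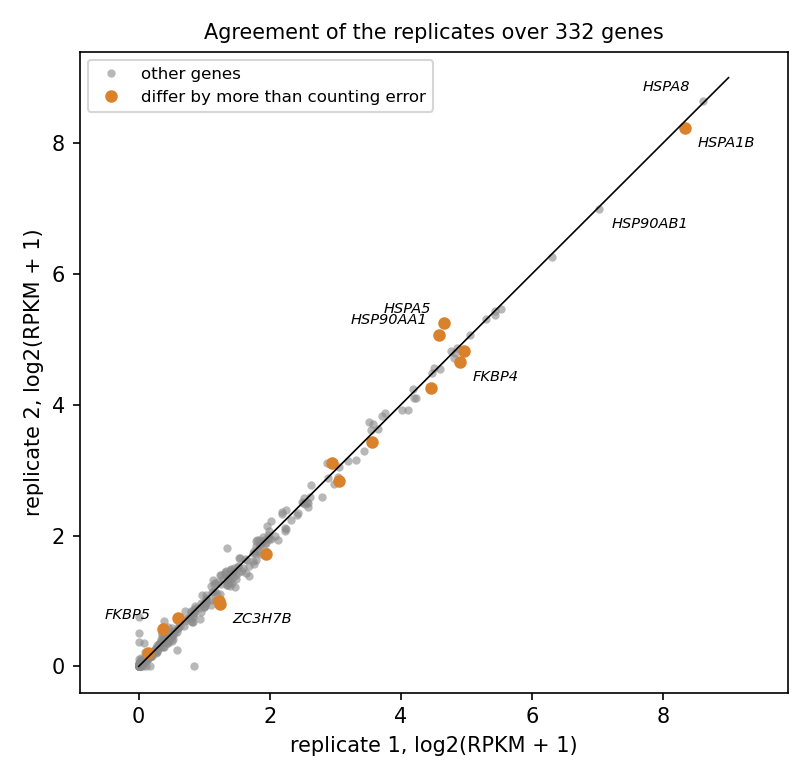
RPKM of 332 genes in replicate 1 (x axis) and replicate 2 (y axis), both as log2(RPKM + 1), with the line of equal values. Orange points are the 15 genes that differed by more than counting error, among them HSP90AA1 and HSPA5 above the line.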

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

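Calculations with exonic length, with reads alone, with the HSPA1B windows and with lists lacking HSPA1A and HSPA1B were chosen after the data were seen, the others before. Of 146 recalculated values, 125 kept their direction and side of the threshold or stayed within the replicate spread. For counts of genes or lists the limit was 1.5 times. Of the others, 9 moved, 6 fell short of the threshold, 5 newly passed it and 1 reversed. Some of the 125 could hardly change. Among them were lists that hold neither HSPA1A nor HSPA1B recalculated without these genes, the removal of duplicate symbols and the rescaling of replicate 2. Where a value changed, the cause was not tested unless stated. With exonic length, which was shorter than the span for most genes, 247 genes instead of 154 reached 1 RPKM. The list percentiles became 95.39 for HSP70 exchange factors, 98.03 for HSP90 co-chaperones and 97.69 for mitochondrial chaperones, which were no longer called, and 1.045 for tetratricopeptide-repeat proteins, which were. The share of the 10 highest genes was 36.8% with exonic length, 36.2% with reads alone, and 58.1% to 58.2% with either replicate left out, against 58.0%. A threshold of 5 RPKM left 47 genes and one of 0.5 RPKM 186. The lists called were 12 with a pseudocount of 0.1 RPKM and the mean, 10 against lists from outside and 7 with exonic length. With only genes of at least 1 RPKM, 4 lists were called instead of 9, with percentiles of 88.65 for exchange factors, 78.36 for co-chaperones and 89.68 for mitochondrial chaperones; this setting has fewer genes, and left too few small heat shock and tissue-restricted genes for a value. With a pseudocount of 0.1 RPKM and the mean, the HSP70 list (99.28), endoplasmic reticulum list (98.58) and tetratricopeptide-repeat list (0.58) passed, the last also against lists from outside it (0.43). HSPA8 minus HSPA1B reversed to -1.22 with HSPA1B reads placed only in its own windows. With a pseudocount of 0.1 RPKM, Pearson's r was 0.988, the SD of the log2 ratio 0.37, and 7 genes exceeded 2-fold, since low counts then weigh more. Depth limits the low genes: 65 and 68 genes had under 10 reads. No paired analysis was possible because there is 1 group.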

Other observations

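The tests of stress responses in replicate 2 and of genomic span on the CCT ring were chosen after the results were seen, and the gene families in the next paragraph were chosen after their values were seen.

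Several gene families, grouped here by symbol, were not fixed lists of their own, although some members were in those lists. Of the genes of the cyclophilin family, not all of which need be active isomerases, 12 of 18 reached 1 RPKM. They were led by PPIA at 27.0 ± 0.628 RPKM (SD, n = 2), PPIB of the endoplasmic reticulum at 22.2 ± 0.620 RPKM and the mitochondrial PPIF at 15.2 ± 1.52 RPKM. Of the genes with FKBP symbols, among them FKBP9P1, 7 of 17 reached 1 RPKM, led by the HSP90 co-chaperone FKBP4 at 26.6 ± 3.43 RPKM. Of the torsin ATPases 4 of 5 did so, and of the interferon-induced IFIT genes 1 of 5, IFIT5 at 3.79 ± 0.332 RPKM. With exonic length the counts were 15 of 18 for the cyclophilins and 12 of 17 for the FKBP genes, and stayed at 4 of 5 and 1 of 5 for the other families. GTF3C3, a subunit of the RNA polymerase III factor TFIIIC, stood at 1.48 ± 0.0506 RPKM.

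HSPA1A held 4 reads over both libraries beside 5540 and 3356 reads at HSPA1B. If both genes were transcribed alike and every shared read had been counted at HSPA1B, HSPA1A would have kept about 1415 reads. The reason is that 27.4% of its 50-base windows are absent from HSPA1B. Sharing alone therefore does not account for the gap between the annotated transcripts. The windows do not cover RNA of a tagged HSPA1A transgene, which need not hold the differing parts. Whether the line with that transgene was sequenced is not given, so transgene reads counted at HSPA1B stay open. In the annotation used here, 0% of the exonic bases of HSPA1A lie in exons of another gene on the same strand. For HSPA1B, which holds the reads, this share was 36.49%. Same-strand overlap in this annotation therefore does not account for the gap either. Overlap on the other strand or in another annotation stays open, since the authors' strand treatment and annotation release are not given. A lower transcription of HSPA1A, a sequence difference of the cell line in the differing parts and reads shorter than 50 bases also stay open and may act together. No biological explanation was tested, since there is 1 group.

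HSPA5, HSP90AA1, FKBP5 and CWC27 took a larger share of reads in replicate 2 by at least 0.5 on the log2 scale and passed the binomial test, while ZC3H7B moved the other way (-0.55) and genes such as EMC2 (0.51) did not pass. A stress response of the endoplasmic reticulum may raise HSPA5, but the other 32 genes of that list with at least 100 reads had a median log2 ratio of -0.049 (upper quartile 0.058), and for a heat shock response the other 12 heat-inducible genes had a median of 0.048 (upper quartile 0.13), so both speak against a general response. Removing a trend on GC content and length over 232 genes left 95.2% of the median shift of the 4 genes, from 0.60 to 0.57. A response of few genes and a difference in handling stay open. No biological explanation was tested by a group.

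The 8 CCT ring subunits, which assemble in equal numbers, spread over a 4.10-fold range of RPKM. With exonic length the range was 1.84-fold, so introns in the denominator may be a source of the spread if the counts hold exonic reads only. The same change did not narrow the range of the 6 prefoldin subunits, which went from 4.21-fold to 56.7-fold, so exonic length is no general remedy. The latter rests largely on PFDN5, with 26 and 12 reads over 3380 exonic bases and 0.963 RPKM with exonic length. The next lowest subunit, PFDN6, stood at 8.70 RPKM and the highest, VBP1, at 54.6 RPKM. No biological explanation was tested.

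Of 332 genes, 3 shared at least 50% of their exonic bases with another gene on the same strand, TXNDC5, HSPB2 and TTC4. They had a median of 4.82 reads per exonic kilobase against 60.5 in the 314 genes that shared under 10%, and on the log2 scale with 1 read added to each gene the medians differed by -3.57 (exact permutation p = 0.212). A bound of 90% was tried first and held 0 genes, so 50% was chosen after that was seen.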
